A study of Mus musculus with 30 samples.

How the data were processed

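RNA from 30 cultures of the mouse preadipocyte line 3T3-L1 was measured by RNA sequencing. There were 6 groups of 5 cultures, a control group and a group given quizalofop-p-ethyl (QpE) at 50 µM for each of 6 h, 24 h and 12 days. Per the labels' protocols, every RNA sample had an integrity number of 10, 100 ng of total RNA entered a directional poly(A) library kit with 13 cycles of PCR, samples were randomised before library preparation, and paired reads of 75 bp were made from 1 pool. The labels number the culture replicates 1 to 5 in each group.

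The authors deposited FPKM values (fragments scaled to transcript length and library size) per transcript, in 1 table for all libraries. HISAT, HISAT2, StringTie and the mouse build GRCm38 are named per the submitters' processing notes, with no versions; the settings of alignment and assembly, and whether strand was used, are not given in the sources used here. The table held 150146 transcripts, of which 133887 had Ensembl identifiers and 16259 were assembled transcripts with no gene name. In 10 libraries the deposited FPKM held 11 values just below 0 (lowest -7e-05), which were set to 0. FPKM are not counts, so no count model was used.

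Transcript FPKM were summed per gene. An unnamed transcript was joined to the only named gene of its locus, which placed 10567 of them. This gave 57490 gene rows, of which 14626 (12969 named) reached 1 FPKM in at least 5 libraries and were tested. Values were tested as log2(FPKM + 1), so fold changes are on that scale and understate the change of genes of low level. The test was limma with a mean-variance trend, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p, two-sided. The planned fit took all 30 libraries, with 1 spread per gene shared by all groups and 24 residual degrees of freedom. Gene lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. There were 32 fixed lists, 26 of them large enough to test. Designs, lists, the rule for named genes and most alternatives were fixed before the data were examined.

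The fits were tested on simulated data with the real means and spreads, with 200 of 14626 genes changed, over 10 runs. For QpE at 12 days the planned fit recovered 62.4% of genes changed by 1.5-fold, 83.9% of those changed by 2-fold and 97.4% of those changed by 4-fold, but 52.6% of its calls were false. With a smoother model of the spread, 24.7% of its calls were false. A fit of the compared groups only, made 7.7% and 5.4% false calls under these models and recovered 35.7% of genes changed by 1.5-fold and 69.9% of those changed by 2-fold. Weights per group made 30.7% and 4.6% false calls. These shares hold for 200 changed genes and do not give the share among the real calls. Values were drawn independently for each gene and library. No effect was shared by libraries of the same replicate number or by a set of cultures, and genes were not correlated. The shares may therefore differ in the real 12 day libraries, where such structure was seen. The median SD within a group was 0.281 in QpE at 12 days and 0.158 to 0.215 in the other groups. Because of the false calls, counts of genes called with QpE at 12 days are given from both fits, overall and for each list (those under other settings are from the planned fit unless said), and a gene is said to have risen or fallen with QpE at 12 days only where both fits called it. For QpE at 6 h and 24 h the planned fit made 13.4% and 13.3% false calls (1.6% and 1.8% with the smoother model) and recovered 57.5% and 57.6% of genes changed by 1.5-fold. The contrasts between controls, the interactions and the fits with a block were not simulated.

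Depth was estimated from the steps between low FPKM values of single-exon transcripts, taking 150 bases per pair. It ranged from 9.5 to 17.5 (in units of 1e+06 fragments) per library, with 72.8% to 87.7% of low values being whole multiples of the step within 0.004 FPKM times bases. The estimate is approximate and no interval was drawn from it. Libraries of a group correlated with a mean r of 0.940 to 0.960 across genes, and no pair of libraries was identical (highest r within a group 0.966).

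Replicate numbers were checked for pairing by correlating deviations from the group means between control and QpE libraries of the same number. At 12 days the correlations were 0.19, 0.19, 0.33, 0.38 and 0.16, all above 0.1, the bound set for pairing, so the numbers are taken to pair the 12 day libraries. This comes from the data, as the labels state no shared day or batch, and only 3 of 5 control libraries at 12 days correlated best with their own number. At 6 h (lowest 0.04) and 24 h (lowest 0.04) they do not.

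Named genes were chosen by a fixed rule. For each QpE contrast these were the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, up to 4 called members per list with the smallest adjusted p, and 8 genes given whatever their result. For contrasts between times, 4 rises and 4 falls were taken by the same rule. Genes without a given name were left out, and 1 named gene is not reported here.

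Alternatives tried were pseudocounts of 0.1 and 4, no filter and a filter at 5 FPKM, median-ratio, quantile and TPM scaling, the compared groups only, the replicate number as a block, robust moderation, the most abundant transcript of each gene only, and leaving out each library. Added after seeing the data were the replicate block with the compared groups only, weights per group, a term for a set of cultures, each set of cultures alone, annotated transcripts only, named genes only, and leaving out 2 libraries. A further 11 gene lists were added after the results of the named genes were seen. Computation used R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.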

Results

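Gene expression was measured in 30 cultures of 3T3-L1, a mouse fibroblast line that turns into fat cells in an adipogenic medium. Cultures in a medium with insulin and a phosphodiesterase inhibitor were left as controls or given 50 µM quizalofop-p-ethyl (QpE), a herbicide, and were sampled under the labels 6 h, 24 h and 12 days, with 5 cultures per group. The protocol describes medium changes over a shorter time than the 12 day label, which is used here as given. FPKM totals ran from 413502 to 500489 per library, and estimated depth from 9.5 to 17.5 in units of 1e+06 fragments.

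The control cultures give the background of change over time. From 6 h to 24 h, genes of the contractile and SRF or YAP target list fell in controls: 12 of 14 tested members fell and none rose (12 adjusted over the list alone; camera adjusted p = 9.57e-16, adjusted p = 0.0707 with an estimated correlation). Ctgf, a YAP target, fell by 3.65 ± 0.34 on the log2 scale (SE, n = 5), from 16.8 ± 12.5 to 0.183 ± 0.180 FPKM (SD), and Actg2, a smooth muscle actin, fell by 3.01 ± 0.24. Cell cycle genes rose, with 18 of 25 members higher (19 adjusted over the list alone; camera adjusted p = 1.41e-12, adjusted p = 0.457 with an estimated correlation). Adipocyte genes had 3 of 24 higher (3 adjusted over the list alone; camera adjusted p = 0.00426, adjusted p = 0.882 with an estimated correlation). Agtr2, an angiotensin receptor, rose by 1.97 ± 0.40. In all, limma called 1070 genes higher and 1308 lower at 24 h. With the most abundant transcript of each gene only, these counts were 433 and 588.

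From 24 h to 12 days the controls took on fat cell transcripts. Of 24 tested adipocyte genes, 22 rose and none fell (23 adjusted over the list alone; median log2 change 2.84; camera adjusted p = 4.27e-20, adjusted p = 0.0730 with an estimated correlation). Cfd, the adipokine adipsin, rose by 4.82 ± 0.78 on the log2 scale (SE, n = 5), from 13.6 ± 8.46 to 581 ± 486 FPKM (SD), and Gpd1, which makes glycerol 3-phosphate, by 4.42 ± 0.89. Oxidative phosphorylation genes rose in 25 of 26 cases (26 adjusted over the list alone; adjusted p = 0.0249 with an estimated correlation), and 23 of 25 cell cycle genes fell (24 adjusted over the list alone; adjusted p = 0.0699 with an estimated correlation). Fatty acid oxidation and PPAR targets rose in 16 of 23 cases (16 adjusted over the list alone; camera adjusted p = 1.55e-10, adjusted p = 0.11 with an estimated correlation) and thermogenic genes in 4 of 5 (4 adjusted over the list alone; 1.59e-06, and 0.00749 with an estimated correlation). The 5 thermogenic genes tested were Ppargc1a, Cox7a1, Cox8b, Kcnk3 and Gk. Most members of that list were not among the genes tested, Ucp1, Cidea, Dio2, Elovl3 and Prdm16 included. Extracellular matrix genes had 2 of 28 higher and 4 lower (2 and 4 adjusted over the list alone) and a median of -0.10. limma called 1886 genes higher and 2863 lower. Median-ratio scaling gave 2308 and 2069, so the share of higher calls went from 39.7% to 52.7%, and the most abundant transcript only gave 1131 and 1479. The mitochondrial ribosomal RNA gene mt-Rnr1 came out as the largest fall, but it was listed at 0 in all 5 control libraries at 12 days and at 0 in 3 of the QpE libraries at that time, so no fold is given.

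At 6 h no gene passed the threshold between QpE and control cultures. The master regulator of fat cell formation Pparg had 22 ± 6.49 FPKM with QpE and 20.7 ± 3.64 in controls (SD, n = 5; log2 difference 0.05, 95% interval -0.37 to 0.47), and Cebpa, its partner, had a log2 difference of -0.12. Acaca and Acacb, which encode the acetyl-CoA carboxylases, differed by -0.12 and 0.05, and Fasn, fatty acid synthase, by 0.02. limma called 0 of 14626 genes, with 265 at an unadjusted p under 0.05 where chance gives 731. A fit of the compared groups only called 1 gene, an unnamed transcript locus (log2 difference 1.72, adjusted p = 4.15e-04), chosen here after its value was seen.

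At 6 h, 4 gene lists shifted upwards by small amounts in camera, though no member was called over all genes or adjusted over the list alone. The members of the amino acid and integrated stress response list had a median of 0.12 (16 of 21 above 0; camera adjusted p = 0.00227, adjusted p = 0.899 with an estimated correlation). Cholesterol synthesis genes had a median of 0.09 (camera adjusted p = 0.00839), contractile genes 0.13 (0.00839) and glucocorticoid targets 0.14 (0.0248), each with adjusted p = 0.975 with an estimated correlation. The number of lists called was 0 without control replicate 5 or without QpE replicate 3, 1 without control replicate 1 or 2, and 7 without QpE replicate 5.

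At 24 h QpE again moved no single gene past the threshold. Abhd5, which activates the lipase that breaks down stored fat, came nearest, with a log2 difference of 0.54 ± 0.09 (SE, n = 5; adjusted p = 0.0660); it was chosen after its value was seen. Pparg had 41.6 ± 8.20 FPKM with QpE and 30.8 ± 5.45 in controls (SD; log2 difference 0.42, 95% interval -0.004 to 0.834, adjusted p = 0.922). Fabp4, a fatty acid binding protein of fat cells, differed by 0.35, Plin1, a lipid droplet protein, by 0.34, and Adipoq, the hormone adiponectin, by -0.07. limma called 0 of 14626 genes, with 784 at an unadjusted p under 0.05 against 731 by chance. Abhd5 was called with median-ratio scaling (adjusted p = 0.0487), with weights per group (0.0435) and without control replicate 1 (0.0266).

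As lists, 9 groups of genes were shifted at 24 h in camera, and none with an estimated correlation. Of 24 adipocyte genes, 21 lay above 0 (median 0.37; camera adjusted p = 0.00116, adjusted p = 0.724 with an estimated correlation). Oxidative phosphorylation genes lay above 0 in 25 of 26 cases (median 0.15; 7.13e-08, adjusted p = 0.609 with an estimated correlation) and cell cycle genes in 24 of 25 (median 0.23; 3.11e-06, adjusted p = 0.696 with an estimated correlation). The other lists shifted upwards were the stress response list (0.19; 0.00116), fatty acid oxidation and PPAR targets (0.17; 0.00203) and pro-adipogenic regulators (0.16; 0.0387), with adjusted p = 0.609, 0.724 and 0.696 with an estimated correlation. Those shifted downwards were extracellular matrix (median -0.19; 0.00732), anti-adipogenic regulators (-0.10; 0.0155) and contractile genes (-0.13; 0.0289), with adjusted p = 0.742, 0.609 and 0.724 with an estimated correlation. None of their members was called over all genes; adjusted over the list alone, 2 anti-adipogenic regulators were lower and the rest had 0. The ribosomal RNA transcript AY036118 stood at 5915 and 9398 FPKM in QpE replicates 1 and 5 at 24 h, and between 930 and 2790 in the other libraries.

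At 12 days QpE changed many genes. Named falls included genes of secreted matrix proteins and of a protease that cleaves matrix. The proteoglycan gene Dcn fell by 2.43 ± 0.41 on the log2 scale (SE, n = 5), from 1106 ± 76.7 to 277 ± 145 FPKM (SD), Lum by 2.55 ± 0.38, Dpt by 2.32 ± 0.50 and the protease gene Mmp3 by 3.33 ± 0.68. The metallothionein genes Mt2 and Mt1, which bind metals, rose by 3.18 ± 0.48 and 2.07 ± 0.36, Ero1l, an oxidase of the endoplasmic reticulum, by 2.00 ± 0.20, and Egln3, an oxygen sensor, by 1.72 ± 0.30. All 8 of these genes were called by both fits (adjusted p between 2.60e-07 and 8.78e-04 in the planned fit, and between 0.00866 and 0.0473 in the fit of the compared groups only). Without QpE replicate 5 the differences were -2.26 for Mmp3, -1.71 for Dcn, -1.88 for Lum and -1.72 for Dpt. Dcn lies on chromosome 10 at 97479609 to 97518143 and Mt2 on chromosome 8 at 94172291 to 94173568 of GRCm38.

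limma with all groups called 1742 genes higher and 2081 lower at 12 days. The fit of the compared groups only called 740 and 1049, and 716 and 1017 genes were called in the same direction by both. With the replicate number, taken from the data to pair these libraries, as a block, the fit of the compared groups only called 1283 and 1500. The labels do not state this pairing, so counts with the block depend on it. In simulated data with 200 changed genes, the first of these fits made a mean of 51.2 to 180.3 false calls per run at 12 days. These were 24.7% to 52.6% of its simulated calls, and the share among the real calls was not estimated. Of 107 named genes called by the planned fit, 38 were not called by the other. The share of higher calls moved with scaling, from 45.6% to 29.4% with TPM scaling (1097 higher and 2633 lower) and to 52.8% with median-ratio scaling (2145 and 1917), so which direction held more genes is not settled; the most abundant transcript only gave 954 and 1103. Within replicates 1, 2 and 5 alone 1601 genes were higher and 2110 lower, and within replicates 3 and 4 alone 1362 and 1389; these sets stood apart in a principal component.

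**Figure D1:**
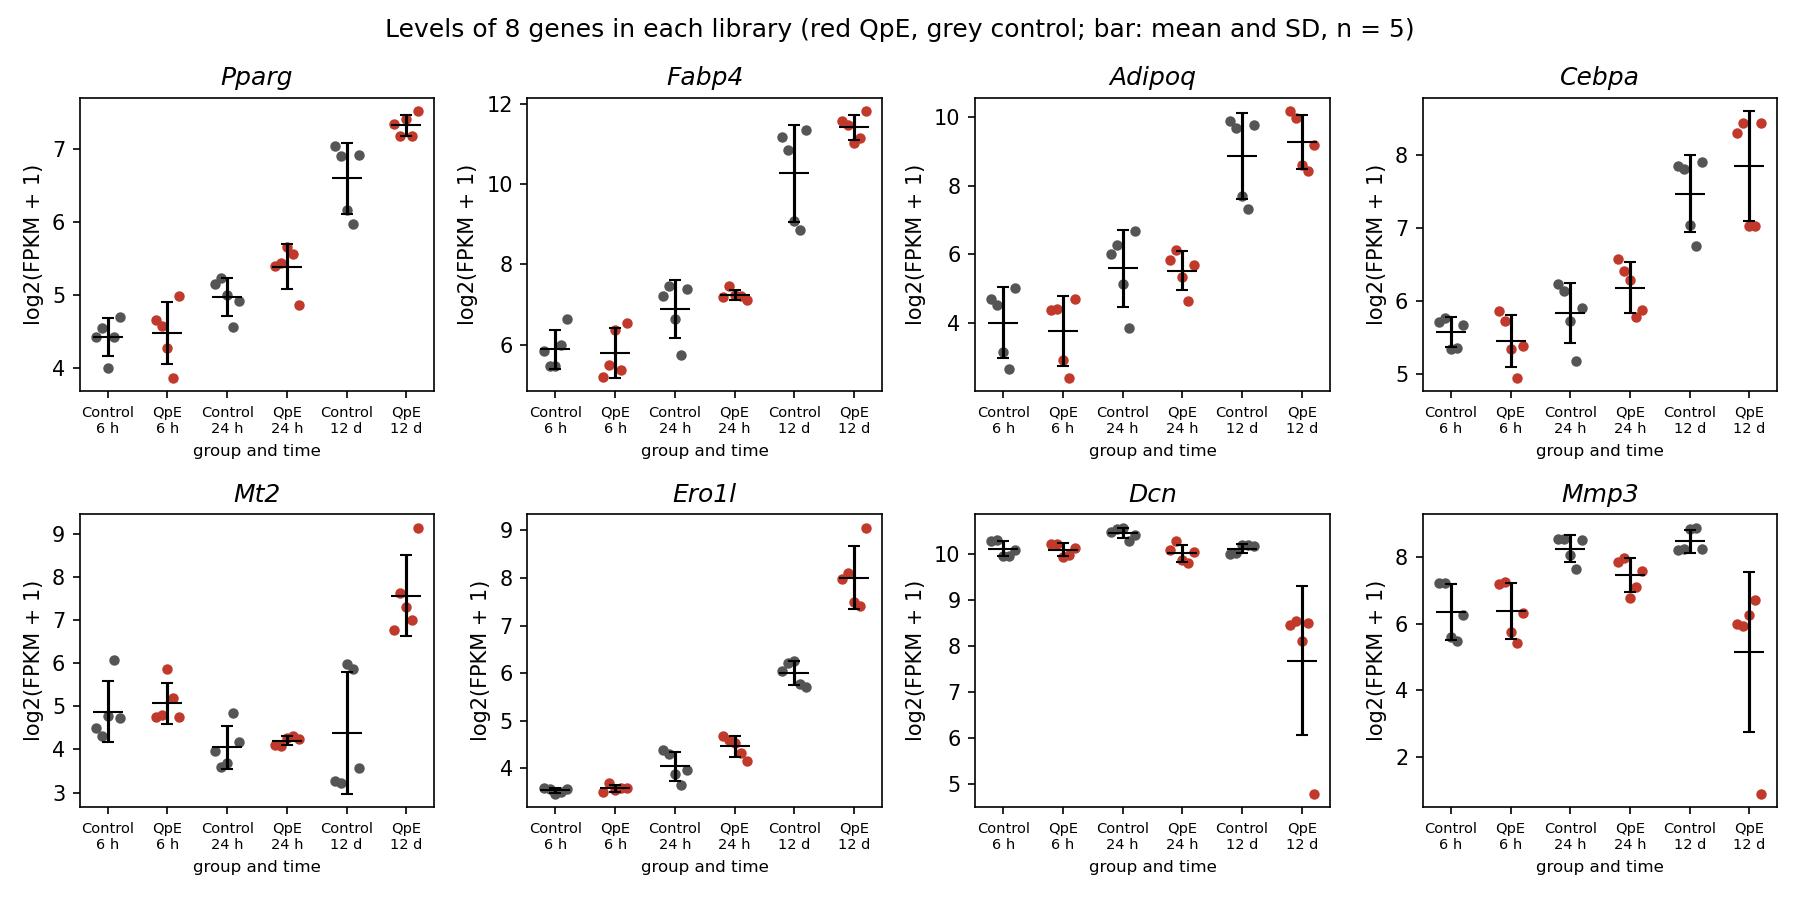
Each of 8 panels plots log2(FPKM + 1) of 1 gene in each library (points, red for QpE and grey for control) by group and time, with the mean and SD of 5 cultures as a bar. Dcn and Mmp3 are lower in the 5 QpE cultures at 12 days than in their controls, and Mt2 and Ero1l are higher.

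Most fat cell genes called at 12 days were higher with QpE, but which genes were called depended on the fit. Pparg was 161 ± 16.3 FPKM with QpE and 101 ± 31.7 in controls (SD, n = 5), a rise of 0.73 ± 0.20 on the log2 scale (SE; adjusted p = 0.00867, and 0.0481 in the fit of the compared groups only). With its most abundant transcript only, its difference was -0.70 (adjusted p = 0.582). Cebpa (0.37), Adipoq (0.40), Plin1 (0.21), Acaca (0.61), Acacb (0.47) and Fasn (0.64) did not pass in either fit, and Fabp4 (1.15, in a locus that holds 4 genes) passed in the planned fit only (0.0361 and 0.169) and not without QpE replicate 5 (1.05, 0.0916). Acaca, Acacb, Fasn and Fabp4 were higher with QpE in all 5 pairs of cultures of the same number, Acaca by 0.50 to 0.69. Cebpa and Adipoq were higher in 4 of 5 pairs (Adipoq from -0.58 to 1.12) and Plin1 in 3 of 5 (-0.42 to 0.89). With the pairs as a block in the fit of the compared groups only, Acaca (adjusted p = 0.0160) and Fasn (0.0398) passed. Acacb (0.0595), Fabp4 (0.0601), Cebpa (0.0595), Adipoq (0.288) and Plin1 (0.488) did not. In the planned fit with the block Acaca (0.0716) and Fasn (0.292) did not pass. Of 24 adipocyte genes, 5 were called higher by the planned fit and 4 by both (5 adjusted over the list alone; camera adjusted p = 0.0156, adjusted p = 0.676 with an estimated correlation). With the replicate number as a block, 11 were called higher and 1 lower. The fit of the compared groups only with the block called 12 higher and 0 lower (camera adjusted p = 8.62e-06, adjusted p = 0.357 with an estimated correlation). Both fits with the block called 10 higher and 0 lower. Leaving out 1 culture gave 8 higher (control replicate 1 or QpE replicate 3), 9 (QpE replicate 4) or 3 (control replicate 4) in the planned fit, and 1 or 2 by both fits without any of control replicates 2 to 5 or QpE replicate 1. The 4 called by both fits were the lipase gene Pnpla2 (1.54), Fabp5 (1.00), Agpat2 (0.90) and Dgat1 (0.54). Among regulators that hold back fat cell formation, 10 of 15 were called lower and 1 higher by the planned fit, and 8 lower by both (10 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.62e-06, adjusted p = 0.0546 with an estimated correlation). Without QpE replicate 5 the last value was 0.00863. Dlk1 fell by 1.54 ± 0.20 and Twist1 by 1.44 ± 0.14.

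Extracellular matrix genes had a median log2 difference of -1.44 at 12 days. Of 28, 20 were called lower and none higher by the planned fit, and 16 lower by both (21 adjusted over the list alone; camera adjusted p = 4.35e-13, adjusted p = 0.222 with an estimated correlation). Lox, which crosslinks collagen, fell by 1.72 ± 0.19 and Col5a1 by 0.88 ± 0.12. Inflammatory and NF-kB genes had 12 of 19 lower, 6 by both fits (12 adjusted over the list alone; camera adjusted p = 2.08e-05, adjusted p = 0.222 with an estimated correlation); the chemokine genes Cxcl5 and Cxcl1 fell by 2.11 ± 0.38 and 1.95 ± 0.36 (without QpE replicate 5, Cxcl5 differed by -1.53). Interferon-stimulated genes had 6 of 16 lower, 1 by both fits (9 adjusted over the list alone; 0.00421, adjusted p = 0.448 with an estimated correlation). QpE replicate 5 lay far below the other QpE cultures in its mean matrix level, at 4.91 against 6.60 to 6.96 on the log2 scale, and without it 18 matrix genes were called lower, with a median of -1.06 (17 by both fits; camera adjusted p = 4.56e-16, and 0.0123 with an estimated correlation). The matrix count by both fits was 6 to 9 without any 1 control culture, where the planned fit called 19 to 21. The count of inflammatory genes by both fits was 1 or 2 without any 1 control and 3 without QpE replicate 1 or 5, and with the pairs as a block the fit of the compared groups only called 13 inflammatory and 8 interferon-stimulated genes lower.

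Of 26 oxidative phosphorylation genes, 25 were called higher at 12 days by the planned fit and 18 by both (26 adjusted over the list alone; median 0.49; camera adjusted p = 1.05e-16, adjusted p = 0.134 with an estimated correlation). By both fits the count was 6 to 8 without control replicate 3, 4 or 5 or QpE replicate 3, and 11 without QpE replicate 1 or 5. Ndufv2, a subunit of complex I, rose by 0.82 ± 0.08 and Cycs, cytochrome c, by 0.92 ± 0.13. Fatty acid oxidation and PPAR targets had 12 of 23 higher and 1 lower in the planned fit but 2 higher and 1 lower by both (16 and 1 adjusted over the list alone; 1.04e-04, adjusted p = 0.473 with an estimated correlation); Decr1 rose by 0.93 ± 0.14 while Cpt1a, which brings fatty acids into mitochondria, fell by 1.13 ± 0.17. Peroxisome genes had 9 of 22 higher and 2 lower, with 1 and 1 by both (11 and 2 adjusted over the list alone; 0.0032, adjusted p = 0.673 with an estimated correlation). The last 2 counts depend on settings and cultures. The planned fit called 4 fatty acid oxidation genes higher with TPM scaling, 5 with quantile normalization, 5 without QpE replicate 5 and 6 and 5 without control replicates 3 and 4. It called 16 with median-ratio scaling and 17 without control replicate 5. It called 1 peroxisome gene higher with TPM scaling, 5 with quantile normalization, and 3 to 5 without control replicate 3 or 4 or QpE replicate 1, 2 or 5. For peroxisome genes the count was 10 with median-ratio scaling and 12 without QpE replicate 4. With the pairs as a block, the fit of the compared groups only called 15 fatty acid oxidation and 8 peroxisome genes higher.

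Stress response genes also moved at 12 days. In the amino acid and integrated stress response list 10 of 21 were higher and 1 lower, with 6 higher by both fits (11 and 2 adjusted over the list alone; camera adjusted p = 2.91e-04, adjusted p = 0.249 with an estimated correlation). Atf3, a transcription factor of this response, rose by 0.98 ± 0.17, Trib3 by 1.11 ± 0.20 and Asns, asparagine synthetase, by 0.79 ± 0.13. The unfolded protein response list had 9 of 19 higher, 3 by both (9 adjusted over the list alone; 9.52e-04, adjusted p = 0.222 with an estimated correlation), glucocorticoid targets 6 of 14 higher and 1 lower, 5 and 1 by both (6 and 1 adjusted over the list alone; 0.00392, adjusted p = 0.448 with an estimated correlation), and NRF2 targets 5 of 23 higher, 2 by both (4 adjusted over the list alone; 0.0296, adjusted p = 0.676 with an estimated correlation). With TPM scaling or quantile normalization 5 unfolded protein response genes were higher and 1 lower, and 3 NRF2 targets were higher, as also without QpE replicate 5. By both fits the stress response count was 3 without control replicate 2 or 4, and the glucocorticoid count 2 or 3 without any 1 control or QpE replicate 3. With the pairs as a block, the fit of the compared groups only called 11 stress response genes and 5 NRF2 targets higher. The remaining lists were not called: fatty acid synthesis had 3 of 18 higher and 1 lower (camera adjusted p = 0.0687), cholesterol synthesis 1 of 23 higher and 4 lower (0.809), and AhR targets 3 of 7 lower (0.305). Cell cycle genes had 2 of 25 lower (0.476), p53 targets 2 of 14 higher and 3 lower (0.52), heat shock genes 3 of 14 higher and 2 lower (0.476), and LXR targets 2 of 8 higher and 1 lower (0.476). Xenobiotic enzymes had 3 of 12 higher and 3 lower (0.321), pro-adipogenic regulators 3 of 16 higher and 1 lower (0.321), and thermogenic genes 1 of 5 higher (0.196). DNA methylation enzymes had 3 of 7 lower (0.285), and none of 12 mitochondrially encoded genes was called (0.739). Contractile genes had 1 of 14 higher and 3 lower (0.081), and immediate early genes 2 of 14 higher and 3 lower (0.327); with the replicate number as a block, 5 were lower in each. Adjusted over the list alone, these counts of higher and lower genes were 1 and 3 for cholesterol synthesis, 3 and 2 for LXR targets, 5 and 3 for xenobiotic enzymes, 3 and 3 for heat shock, 1 and 4 for contractile genes and 2 and 4 for immediate early genes, and did not differ for the other lists not called. By both fits the counts of higher and lower genes were smaller: 1 and 1 for fatty acid synthesis, 0 and 1 for cholesterol synthesis, AhR targets and DNA methylation enzymes, and 0 and 0 for cell cycle, p53 targets and thermogenic genes. They were 3 and 0 for heat shock, 1 and 0 for LXR targets, 1 and 1 for xenobiotic enzymes, 2 and 0 for pro-adipogenic regulators, 0 and 2 for contractile genes and 1 and 2 for immediate early genes. Without QpE replicate 5 the planned fit called 1 gene lower in each of cholesterol synthesis, AhR targets, DNA methylation, xenobiotic enzymes and cell cycle, none lower in heat shock, and 1 higher in immediate early and in mitochondrially encoded genes. These small counts moved with other cultures too, between 1 and 6 lower for cholesterol synthesis, 0 and 5 lower for heat shock and 2 and 6 higher for fatty acid synthesis over all cultures left out. With the pairs as a block in the fit of the compared groups only, 8 fatty acid synthesis genes were higher and the list was called (camera adjusted p = 1.87e-04, adjusted p = 0.131 with an estimated correlation). The planned fit with the block did not call it (3 higher and 1 lower, camera adjusted p = 0.0582), and 3 genes were higher in both fits with the block. Of markers of other cell types, 2 macrophage genes and 1 endothelial gene were tested and not called, and no epithelial gene passed the low-value filter. Des, a muscle marker, rose by 0.91, and the bone and cartilage regulators Runx2 and Sox9 fell by 1.22 and 0.94.

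**Figure D2:**
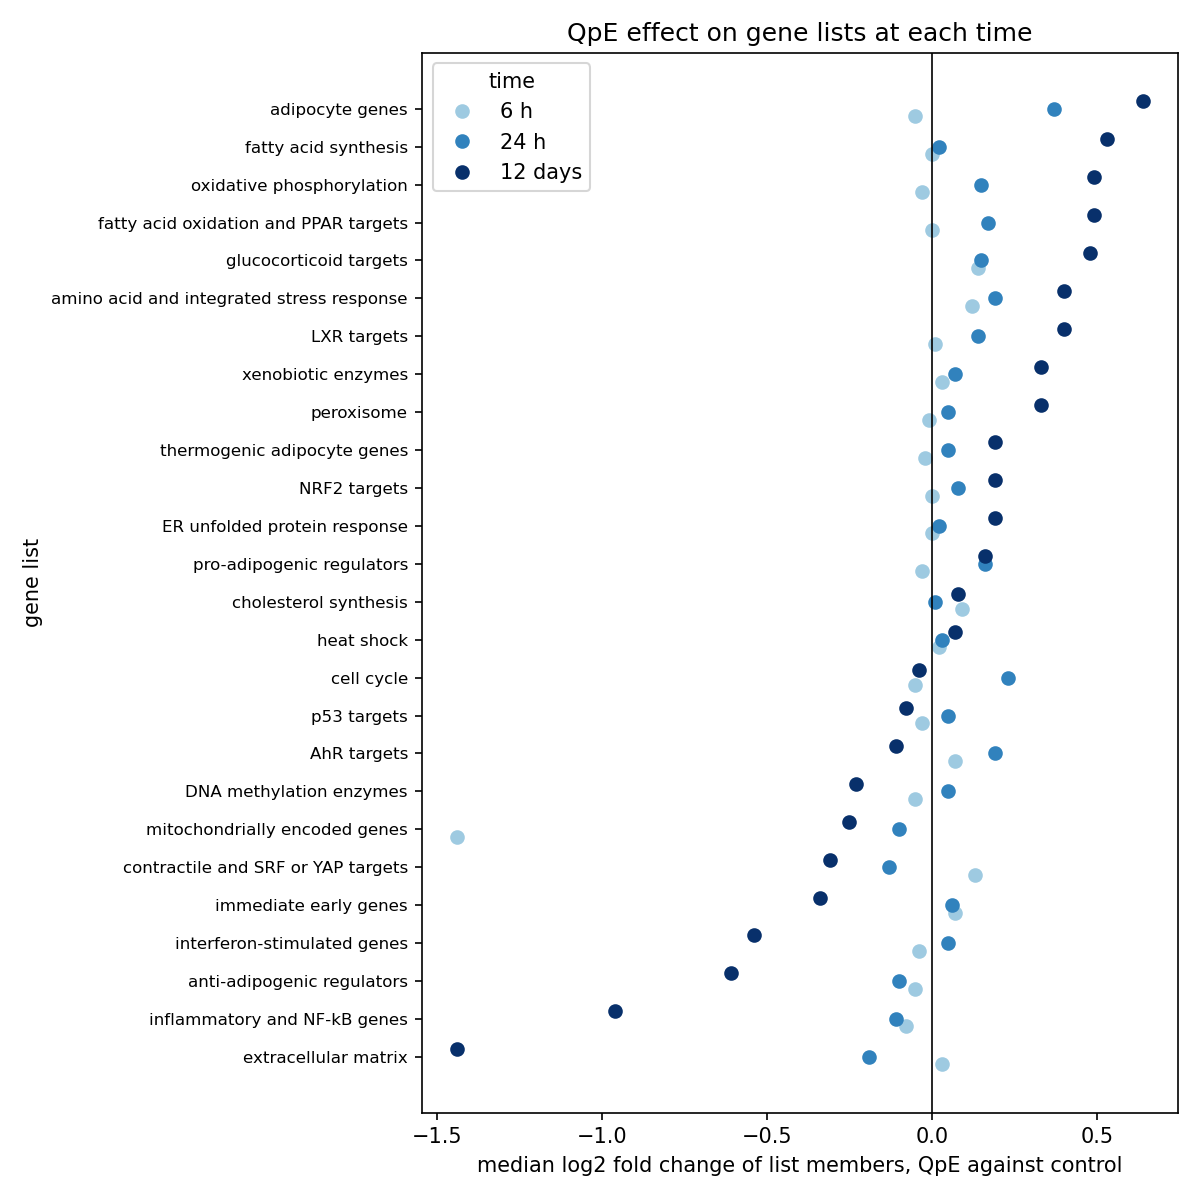
Points give the median log2 fold change of the tested members of each gene list (vertical axis) with QpE against control at 6 h, 24 h and 12 days. The extracellular matrix list lies at 0.03, -0.19 and -1.44, and oxidative phosphorylation at -0.03, 0.15 and 0.49; mitochondrially encoded genes, at -1.44 at 6 h, were not called there (camera adjusted p = 0.196).

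Whether the QpE effect differed between times was tested directly. Between 12 days and 6 h it differed for 1566 genes (673 towards higher and 893 towards lower at 12 days), with Mt2 at 2.99 ± 0.68 and Kera, a matrix proteoglycan, at -2.55 ± 0.50 (difference of log2 fold changes, SE). With TPM scaling 344 were higher and 1266 lower, so the share of higher calls went from 43% to 21.4%. Of 28 extracellular matrix genes 18 differed downwards between 12 days and 6 h (20 adjusted over the list alone; adjusted p = 0.224 with an estimated correlation) and 10 between 12 days and 24 h (18 adjusted over the list alone; adjusted p = 0.256). Between 12 days and 24 h it differed for 739 genes (268 and 471; 36.3% higher, 47.1% with median-ratio and 25.7% with TPM scaling), with Itih4 at 2.49 ± 0.45 and Lum at -2.06 ± 0.54 (-1.39 without QpE 12 day replicate 5), and between 24 h and 6 h limma called 0 genes (426 at an unadjusted p under 0.05, 731 by chance). The compared groups alone gave 899 and 140 genes. The second count was 429 without QpE 24 h replicate 5, 486 without control 24 h replicate 2, 461 without control 12 day replicate 4, 1142 without QpE 12 day replicate 4, and 99 without QpE 24 h replicates 1 and 5. Rpl23a had the largest difference between 12 days and 6 h (6.71; 6.69 without QpE 12 day replicate 5, adjusted p = 0.0773), but it was listed near 0 in some libraries of 3 groups (0.0233 and 0.906 FPKM in QpE at 6 h, 1.34 and 0.271 in controls at 24 h, 0.537 and 0.711 in controls at 12 days) and shares its locus with another gene, so this value is uncertain.

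No call was shared between times, since 6 h and 24 h had 0. Across genes, which are not independent replicates, the log2 fold changes at 24 h and 12 days had r = 0.284, those at 6 h and 12 days 0.056, and those at 6 h and 24 h -0.061. Of 3823 genes called at 12 days, 1729 (45.2%) moved the same way in controls from 6 h to 24 h, against 50.4% of the genes not called (two-sided Fisher's exact test over genes, p = 3.1e-08). Genes are not independent in this test either, so its p does not measure the spread between cultures. Among genes changed by at least 2-fold the share was 37.8%.

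**Figure D3:**
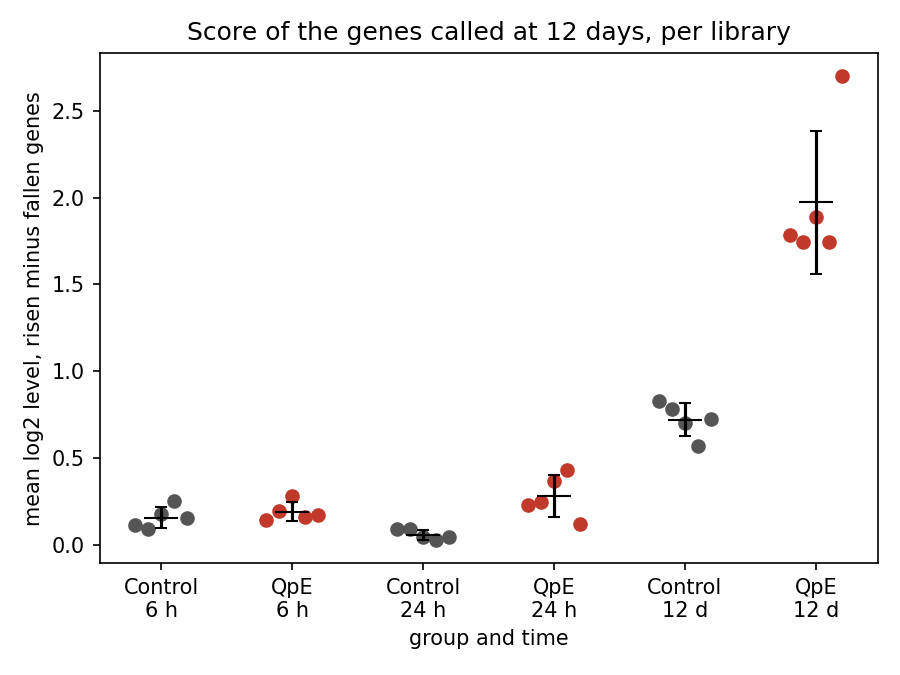
The score of each library is the mean log2 level of the genes called higher minus that of the genes called lower with QpE at 12 days, plotted by group and time with the mean and SD of 5 cultures (red QpE, grey control). The 24 h libraries did not enter the 12 day fold changes, but they did enter the filter and the spread that decided which genes were called. At 24 h the score was 0.281 ± 0.121 with QpE and 0.062 ± 0.029 in controls, and the 12 day groups, which chose the genes, lie apart.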

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

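The tests below chosen only after the result was seen were the other splits of the libraries, the tests of scaling, culture sets, QpE replicate 5 and the course in controls for the matrix genes, and the arrangement, spread and 6 h tests for the 24 h score.

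Extracellular matrix genes were lower with QpE at 12 days, with a median log2 difference of -1.44 over 28 genes. The tables argue against scaling of the libraries (highest median under 3 other scalings -1.40) and against transcript length or expression level, since the lowest median of 10000 random lists matched on both was -0.55. They argue against 1 set of cultures (-1.48 in replicates 1, 2 and 5 and -1.13 in replicates 3 and 4) and against QpE replicate 5 alone (-1.06 without it, 18 of 28 genes called lower by the planned fit and 17 by both). In controls these genes changed by a median of -0.10 from 24 h to 12 days. Control replicates 1, 2 and 5, higher in adipocyte genes, lay at -0.29, -0.25 and -0.2 against the 24 h mean. Control replicates 3 and 4, lower in adipocyte genes, lay at 0 and 0.07. No control culture came near -1.44, which argues against a faster run of the course that controls reached by 12 days. A course that goes further than that of the controls cannot be judged from them alone. QpE replicates 3 and 4 had lower mean adipocyte levels (6.24 and 6.16, log2) than control replicates 1, 2 and 5 (7.58, 7.37 and 7.59). Their mean matrix levels were also lower (6.64 and 6.96 against 7.50, 7.63 and 7.53). For these cultures this argues against a further course as adipocyte genes measure it, though it compares different culture sets. QpE replicates 1 and 2 lay higher in adipocyte genes (7.89 and 7.83), so for them it is left open. A lower level of matrix transcripts in cells given QpE may therefore be biological, as a hypothesis found and tested on the same data.

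Genes called at 12 days were shifted the same way at 24 h, where no gene passed alone, and their score differed by 0.219 between QpE and control libraries at 24 h (exact permutation test, two-sided, p = 0.00794, the smallest that 252 arrangements of 5 against 5 can give). Without QpE replicates 1 and 5, high in AY036118, the difference was 0.288, which argues against these libraries as the cause. Under median-ratio scaling it was 0.218, and doubling all values of a library moves its score by 0.239 at most. A difference of 0.219 from scaling would thus need close to a doubling between the groups, or more. The median log2 difference over all genes at 24 h was 0.011, which argues against 1 scaling factor per library as the cause. Scaling that varies with expression level was not tested for this score. At 6 h the score difference was 0.034 (exact permutation test, two-sided, p = 0.389). The SD of the score within the QpE group at 24 h was 0.121, and the difference there was less than 2 such SDs, short of the bound set. That bound sets the spread of single libraries against a difference of means, so it cannot decide the question. Every QpE library at 24 h (0.124 to 0.431) scored above every control library (0.03 to 0.093). With the permutation test, this argues against spread between cultures alone. The 24 h libraries did enter the spread that decided which genes were called.

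Other splits of the same libraries were drawn, 100 for each comparison with the real split included. For QpE at 6 h and at 24 h, 100 of 100 gave as many calls as the real 0, which a count of 0 fixes, so this says nothing about chance; the highest other counts were 184 and 1, and the 184 at 6 h point to a structure of the samples other than the groups. For QpE at 12 days 1 of 100 gave as many as 3823, and the highest other, 3106, follows the sets of replicates 3 and 4 against 1, 2 and 5, so it points to a structure of the samples; within these sets QpE gave 1362 higher and 1389 lower, and 1601 higher and 2110 lower. Most of the 100 splits put both libraries of some pairs on 1 side, which the real split does not. Of the 16 splits that part all 5 pairs, 1 gave as many and the highest other gave 761, but 16 splits are too few for a share under 0.05. For controls, 1 of 100 gave as many between 24 h and 6 h (2378, highest other 287) and 1 between 12 days and 24 h (4749, highest other 1511), which argues against chance there. These splits did not keep replicate numbers, which do not pair controls across times by the bound used here. Controls of the same number correlated at -0.05 to 0.04 between 6 h and 24 h, and at 0.02 to 0.1 between 24 h and 12 days. For the interactions the counts were 100 of 100 between 24 h and 6 h (0, highest other 2), 1 between 12 days and 6 h (1566, highest other 1153) and 2 between 12 days and 24 h (739, highest other 1750, which also points to such a structure). The first is fixed by its count of 0, and the splits for the other 2 did not keep the 12 day pairs, so no statement about chance is made for the interactions.

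A library lay far from the other 4 of its group in 15 of 88 cases tested. The cases share libraries and include genes chosen for a large change at 12 days, so no share by chance is given. QpE 12 day replicate 5 had the highest score of the genes called at 12 days (2.698), the lowest mean level of matrix genes (4.91 on the log2 scale), the highest FPKM of Mt2 (563.9), Anxa8 (623.2), Itih4 (114.5), Mt1 (884.2), Cib2 (194.4) and Ero1l (531.9), and the lowest of Lum (1.907) and Dcn (26.44). Control 12 day replicate 1 had the highest Zbtb16 of its group (3.127 FPKM). QpE 24 h replicate 5 had the lowest FPKM total of its group (440837) and QpE 24 h replicate 4 the lowest estimated depth (11.2, in units of 1e+06 fragments). Replicate 5 had the most genes at 1 FPKM or more at 6 h, 13414 in controls and 13407 with QpE.

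The QpE effect differed between times by limma's test of the difference for 1566 genes between 12 days and 6 h and for 739 between 12 days and 24 h. Between 12 days and 6 h the named differences of log2 fold changes were 6.71 for Rpl23a, 2.99 for Mt2, 2.83 for Anxa8, 2.49 for Itih4, -3.36 for Mmp3, -2.55 for Kera, -2.49 for Mfap2 and -2.46 for Lum. Between 12 days and 24 h they were 3.03 for Mt2, 2.49 for Itih4, 2.17 for Anxa8, 1.92 for Mt1, -2.42 for Olfml3, -2.10 for Cpz, -2.06 for Lum and -2.06 for Kera. Without QpE 12 day replicate 5 the first set lost the calls of Rpl23a (6.69, adjusted p = 0.0773) and Mfap2 (-2.21, 0.0649), and the later set those of Mt1 (1.60, 0.0549), Olfml3 (-2.02, 0.0651) and Cpz (-1.83, 0.0804). Without it Mmp3 differed by -2.29 against 6 h, and Lum by -1.79 against 6 h and -1.39 against 24 h.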

How the results depend on the processing

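The tests chosen only after the result was seen were weights per group, the culture set as a covariate or alone, annotated transcripts only, named genes only, the block with the compared groups only and leaving out 2 libraries. Of values for named genes and lists, 4008 kept their direction and side of the threshold, 371 lost the call, 12 gained it and 3 changed direction: Pparg at 12 days (-0.70, adjusted p = 0.582) and Dnaja1 (0.024, 0.951) with the most abundant transcript only, and Cdkn1a (-0.32, 0.105) in replicates 3 and 4 only. Of summary counts, 420 stayed within 1.5 times and 55 did not, given below; the cause was not tested except where fewer libraries or transcripts entered. Precision of low genes is limited by a depth estimated at 9.5 to 17.5 (in units of 1e+06 fragments). In order, interaction counts are those of 12 days against 6 h and against 24 h.

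No filter gave interactions of 997 and 330 and 1 list at 6 h. Median-ratio scaling gave 1 gene higher at 24 h, and TPM scaling 1097 higher at 12 days. The compared groups only gave 1 gene higher at 6 h, 740 higher and 1049 lower at 12 days, and interactions of 899 and 140. The most abundant transcript only gave 1 higher at 24 h, 954 higher and 1103 lower at 12 days, interactions of 635 and 227, 433 and 588 in controls from 6 h to 24 h, 1131 and 1479 from 24 h to 12 days, and 4 lists at 24 h. Lists called were 0 at 6 h, 24 h and 12 days with an estimated correlation, 0 at 6 h and 24 h with fry, and 0, 0 and 20 with fry in either direction. At 12 days fry called 11 lists, which stayed within 1.5 times. Weights per group gave 1 higher at 24 h, 1010 higher at 12 days and 1702 higher in controls at 24 h. The culture set as a covariate gave 1 higher at 24 h and 1109 genes for the later interaction. Annotated transcripts only gave 464 for that interaction, 710 higher in controls at 24 h and 2 lists at 6 h. Without the 2 QpE 24 h libraries high in AY036118 it was 99. Replicates 1, 2 and 5 only gave 2 higher and 1 lower at 6 h, and replicates 3 and 4 only 3 and 1 at 6 h, 13 and 16 at 24 h and 0 lists at 6 h.

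With the replicate number as a block, counts at 12 days were 1966 higher and 2239 lower, interactions 1965 and 1026, controls 1251 and 1488, then 2037 and 3088, and lists called 3, 9 and 12; with the compared groups only, the block gave 1 gene higher at 6 h and 1283 higher and 1500 lower at 12 days, where against that fit without the block 26 of 113 named genes gained the call and 3 lost it. In the planned fit the block changed no call of a named gene or list at 12 days. Beyond the list counts given with the results, it moved only those of stress response genes called lower (1 to 2) and NRF2 targets called lower (0 to 1) by over 1.5 times. At 6 h and 24 h the samples share only a number (4 of 5 control libraries at 6 h and 3 of 5 at 24 h correlated best with their own).

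Leaving out each library in turn gave 1300 to 1781 higher and 1596 to 2185 lower at 12 days, 0 to 1 higher at 24 h, interactions of 1180 to 1942 and 429 to 1142, controls 726 to 1160 and 991 to 1237, then 1621 to 1899 and 2473 to 2819, and lists 0 to 7 at 6 h, 6 to 9 at 24 h and 10 to 13 at 12 days. Without QpE 12 day replicate 5 named calls lost in the planned fit included Mmp13, Fabp4, Rxra, Scd1, Sc5d, Cyp1b1, Ugt1a7c, G6pdx, Dnaja1, Mcm4, Dnmt1, Uhrf1 and Alpl.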

Other observations

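Lists of genes in this part were all chosen after the results of single genes were seen, and so were their tests. Their adjusted p was taken over these lists only, with the hypoxia list entered with and without 2 of its genes. It is therefore not comparable with that of the 26 fixed lists. Of those, 0 passed with an estimated correlation at 12 days in the planned fit of all libraries. Genes of the tricarboxylic acid cycle, which feeds the respiratory chain, were called higher with QpE at 12 days in 17 of 18 cases by the planned fit and 10 by both fits (median log2 difference 0.55; camera adjusted p = 2.22e-12, 0.0375 with an estimated correlation, but 0.112 in the fit of the compared groups only). Genes of the mitochondrial ribosome were higher in 17 of 19 cases, 11 by both fits (median 0.48; 0.00784 with an estimated correlation, but 0.0864 in the fit of the compared groups only), and mitochondrial import and chaperone genes in 13 of 17, 9 by both (median 0.36; 0.00784, and 0.0173 in the fit of the compared groups only). Glycolysis genes were higher in 7 of 14 cases, 5 by both (median 0.79; 1.6e-05, adjusted p = 0.0510 with an estimated correlation), and proteasome genes in 8 of 17, 4 by both (median 0.19; 0.0375, and 0.0173 in that fit). Genes that break down branched-chain amino acids were higher in 12 of 17 cases, but 2 by both fits (1.33e-06, adjusted p = 0.153 with an estimated correlation) and 4 and none without QpE replicate 5. With the replicate pairs as a block, the fit of the compared groups only called 14 of these genes higher. With this block no list of this part was called with an estimated correlation, import and chaperone genes and proteasome genes included (0.131 each). By both fits, leaving out 1 culture gave 5 to 10 tricarboxylic acid cycle genes, 8 to 13 of the mitochondrial ribosome, 5 to 9 of import and chaperones, 1 to 6 of glycolysis and 1 to 4 of the proteasome.

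Genes of Wnt receptors and modulators were lower in 9 of 12 cases, 7 by both fits (median -0.71; camera adjusted p = 1.55e-07, 0.00784 with an estimated correlation, but 0.0674 in the fit of the compared groups only), and genes of the TGF-beta pathway in 11 of 15, 7 by both (median -0.64; 0.0267 with an estimated correlation, but 0.0864 in that fit). The Wnt list holds receptors such as Fzd1 and Fzd2 and modulators such as Sfrp2 and Dkk3. Whether the activity of that pathway changed was not tested. Hypoxia-responsive genes were higher in 7 of 16 cases and lower in 1, 5 higher by both fits (8.52e-05, 0.0467 with an estimated correlation, but 0.163 in that fit). Without Ero1l and Egln3, the genes that led to the choice of this list, 5 of 14 were higher and 1 lower, 3 and 0 by both fits (0.00299, adjusted p = 0.0909 with an estimated correlation). Complement genes were lower in 3 of 7 cases, 2 by both fits (0.0138, adjusted p = 0.0909 with an estimated correlation), and the lysosome list was not called (0.404). By both fits, leaving out 1 culture gave 4 to 8 Wnt and 3 to 7 TGF-beta genes lower.

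The mean log2 level of adipocyte genes at 12 days was 7.58, 7.37, 5.43, 5.07 and 7.59 in control replicates 1 to 5 and 7.89, 7.83, 6.24, 6.16 and 7.43 in the QpE replicates of the same numbers. The share of FPKM from mitochondrially encoded genes ran from 0.15% to 3.6% per library.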
